A study of Caenorhabditis elegans with 6 samples.

How the data were processed

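Small RNA was sequenced from embryos of Caenorhabditis elegans of 2 genotypes, a dot-1.1 ced-3 double mutant and a ced-3 single mutant, with 3 libraries called biological replicates in the labels for each. Per the labels' protocols, embryos were isolated from synchronised egg-laying adults grown at 20 °C with a hypochlorite solution, total RNA was extracted, inserts of 18 to 40 bases were selected, and single reads of 50 bases were sequenced. The submitters' processing notes name the genome build WBcel235. The aligner, the counting program and the treatment of reads that fit several places are not given in the sources used here.

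The authors deposited 2 tables of raw counts, with whole-number read counts per gene, 1 column per library and 32238 genes in each. One table's name says antisense and the other's names no strand. Columns were matched to samples by genotype and replicate number, and no per-library column was left unused. For replicates 2 and 3 the short names in the sample titles carry other numbers than the columns, so which sample of a genotype is replicate 2 or 3 is uncertain, while the genotype is not. Of 216 microRNA genes with no annotated exon on the other strand, 99.98% of counts lay in the first table, which was therefore read as the sense table. Some reads were counted in both tables. T09B4.14, a non-coding gene across from mir-1, had 15482048 antisense counts where mir-1 had 15482050 sense counts, and it made up 47.0% of all antisense counts. Between 86.9% and 89.9% of a library's antisense counts lay in genes whose exons overlap an exon on the other strand, so antisense counts of such genes cannot be told apart from sense reads of their partner.

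Gene classes were taken from the RefSeq gene table of WBcel235, in which 31418 of the genes were matched, 30524 by symbol and 894 by sequence name. Strands and exons came from the Ensembl annotation of the same build, in which 31445 genes were matched to 1 gene by name, position or transcript name, and gene positions came from it for these genes. The tables held 0 piRNA genes. Total counts ranged from 19206363 to 26409182 in the sense table and from 4891289 to 6568937 in the antisense table. No sequence of the genome was used, so identity between gene copies was judged by their lengths and positions alone.

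Each table was tested with edgeR 4.0.16 in R 4.3.3, with its filter on low counts, TMM normalization from the table's own counts and a robust quasi-likelihood F test of genotype over all 6 libraries. Benjamini-Hochberg adjusted p under 0.05 was the threshold. The standard error of a log2 fold change was its size divided by the square root of the F statistic. Normalised counts are counts per 1000000 of the TMM-adjusted library size, given as mean ± SD over 3 libraries. Whether a gene's antisense count changed differently from its sense count was tested as the interaction of strand and genotype with library as a block. Gene lists, 29 in all, were fixed before the data were examined and tested with camera of limma 3.58.1 at a preset correlation of 0.01, at an estimated correlation, and with fry, where at least 5 members passed the filter. The version with an estimated correlation rests on the few residual degrees of freedom of 6 libraries, and how often it recovers a changed list was not simulated. The p-values measure only the spread between these 6 libraries, with 1 strain per genotype. Shares of counts were compared by a two-sided exact permutation test, whose smallest possible p with 3 libraries against 3 is 0.1.

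The rule for named genes was also fixed beforehand. Where under 8 genes of a table passed the threshold, it takes the 8 with the smallest p, which then do not pass, together with dot-1.1, ced-3, zfp-1, list members past the threshold and the 5 most abundant microRNAs. The genes glb-18, mup-4, unc-13, rgef-1, C38D9.2, vit-1, vit-2, vit-3, vit-5, vit-6, lin-4, myo-3, bli-1, mir-70, pmp-5 and T09B4.14 lie outside this rule and were chosen after their values were seen.

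The procedures were tested on simulated counts with 200 changed genes drawn from the real means, library sizes and dispersions. Of genes changed by 8-fold, edgeR recovered 80.3% among 7297 antisense genes and 60.6% among 7680 sense genes. Of those changed by 4-fold it recovered 26.9% and 25.4%, and of those changed by 2-fold 1.49% and 2.99%. Beside these it made 9 false calls in the antisense and 1 in the sense table. On the same simulated genes DESeq2 recovered 89.4% and 80.3% of 8-fold changes, with 7 and 4 false calls. On the real counts it tested 27264 antisense and 27914 sense genes, a setting that was not simulated. Simulated genes varied independently of one another, so these rates leave out variation shared between genes of a library. In the antisense table the 9 false calls stood beside 53, 18 and 1 true ones at 8-, 4- and 2-fold, more than the 5% that the threshold aims at. The interaction test recovered 10.6% of 8-fold changes among its 13616 genes and 0 of 67 4-fold changes, with 0 false calls. DESeq2 1.42.0, other normalizations and filters, the replicate number as a block, and leaving out each library were run as alternatives.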

Results

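Small RNA libraries were prepared from embryos with a mutation in dot-1.1, which encodes the worm counterpart of the histone H3 lysine 79 methyltransferase DOT1L, in a ced-3 mutant background, and from embryos with the ced-3 mutation alone. CED-3 is the caspase that carries out programmed cell death. The comparison asked which small RNAs differ with the dot-1.1 mutation. Each genotype had 3 libraries. The sense table held 19206363, 22344506 and 20994087 counts in the single mutant and 19659269, 19529265 and 26409182 in the double mutant. The antisense table held 4891289, 6151546 and 5226878 counts in the single mutant and 5214468, 4892780 and 6568937 in the double mutant.

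Counts at the mutated genes were low in both genotypes. Sense counts at dot-1.1 (chromosome I, 2382953 to 2401492, WBcel235) were 75, 66 and 55 in the single mutant and 23, 40 and 32 in the double mutant. Their normalised means were 3.13 ± 1.71 and 1.66 ± 0.673 counts per 1000000 (SD, n = 3), a difference that did not pass (exact permutation test, two-sided p = 0.2). Antisense counts at dot-1.1 were 44, 57 and 40 in the single mutant and 34, 45 and 29 in the double mutant. At ced-3 (chromosome IV, 13198261 to 13204137), which is mutated in both genotypes, sense counts were 5, 1 and 4 against 4, 3 and 5. Small RNA counts summed over a gene do not measure its messenger RNA, and which part of dot-1.1 the allele alters is not given in the sources used here, so these counts do not check the labels. For zfp-1, whose product binds DOT-1.1, the log2 fold change was 0.11 ± 0.43 (SE) in the sense table and 0.16 ± 0.35 in the antisense table, with edgeR adjusted p of 0.963 and 0.951.

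The libraries were mostly microRNA, and the microRNA share varied more within a genotype than between genotypes. MicroRNA genes took 77.8%, 92.4% and 86.7% of sense counts in the single mutant and 72.9%, 79.0% and 89.5% in the double mutant. The means were 85.6% ± 7.37 and 80.5% ± 8.41 (SD, n = 3; exact permutation p = 0.5). Ribosomal RNA genes took 6.32% ± 4.91 and 11.8% ± 6.83 (n = 3, exact permutation p = 0.4), and protein-coding genes 4.77% ± 2.31 and 4.56% ± 1.65 (n = 3, exact permutation p = 1). Transfer RNA genes took 0.644% ± 0.224 and 0.742% ± 0.389 (n = 3, exact permutation p = 0.8). Small nuclear RNA genes took 0.168% ± 0.0280 in the single mutant and 0.110% ± 0.0287 in the double mutant, with no overlap between genotypes (n = 3, exact permutation p = 0.1, the smallest p the design allows, and 0.9 after adjustment over the 9 classes). Protein-coding genes took 10.9% ± 0.656 and 9.98% ± 1.5 of the antisense counts (n = 3, exact permutation p = 0.5). In the sense table the first principal component held 52.6% of the variance and placed replicate 2 of the single mutant and replicate 3 of the double mutant, the 2 libraries richest in microRNA, apart from the others. The second component, with 21.6%, separated the genotypes.

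**Figure D1:**
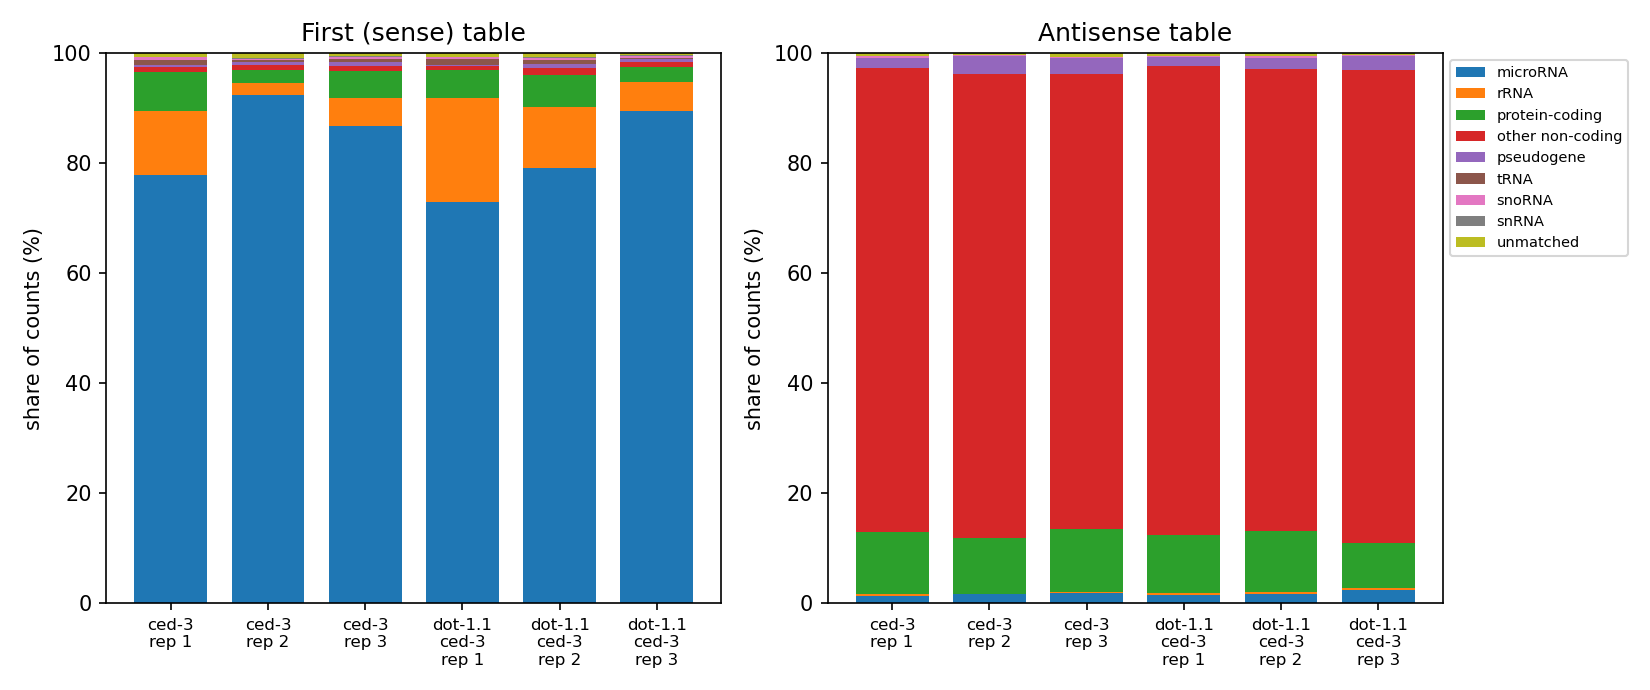
Share of counts (%) taken by each class of gene, stacked in 1 bar per library, for the sense table and the antisense table. Within the single mutant the microRNA share of sense counts ran from 77.8% to 92.4%, a wider gap than that between the genotype means of 85.6% and 80.5%.

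No difference was detectable at this precision in the 5 most abundant microRNAs. They were mir-35, mir-39 and mir-37, of a family needed for embryonic development, together with mir-1, the muscle microRNA, and mir-44. Normalised counts per 1000000 of mir-35 were 153553 ± 91173 in the single mutant and 163901 ± 92236 in the double mutant (SD, n = 3). These values depend on the library scaling, whose TMM factors ran from 0.533 to 1.95. Unscaled, mir-35 had 2521780, 3225742 and 3455650 of 14934846, 20643233 and 18204133 microRNA counts in the single mutant. In the double mutant it had 2559504, 2634527 and 3799762 of 14324396, 15432449 and 23637864. The log2 fold changes ran from -0.21 ± 0.79 (SE) for mir-44 to 0.42 ± 0.88 for mir-39, and the smallest edgeR adjusted p of the 5 was 0.915. With TMM normalization their directions turned when single libraries were left out. Scaled by microRNA counts instead, all 6 libraries gave mir-35 a log2 fold change of -0.014.

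Antisense counts may include the small interfering RNAs that worms make against messenger RNAs. How much of the counts these RNAs make up was not tested, since counts per gene give neither read length nor first base. A lack of calls therefore does not show that such RNAs were unchanged. The test of antisense counts took in 7297 genes. With edgeR, 0 genes were higher and 0 lower in the double mutant after adjustment, and at an unadjusted p under 0.05 there were 212 higher and 170 lower, 5.24% of the genes tested. DESeq2 called 0 higher and 6 lower, and 1 higher and 7 lower when run on the genes edgeR tested. The 6 were AC8.12, AC8.7, Y54E2A.4, ads-1, osm-3 and F07B7.1, all of them among the 8 genes with the smallest p in edgeR.

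None of those 8 genes passed the edgeR threshold in the test fixed beforehand. All 8 passed with edgeR and no low count filter (adjusted p from 3.58e-10 for AC8.12 to 0.00189 for W09B7.1). That setting called 89 genes higher and 25 lower in all and was not simulated. The 8 also passed with DESeq2 on the genes edgeR tested (adjusted p from 5.30e-05 to 0.0424). AC8.12, Y38H6C.21 and AC8.7 passed with edgeR when scaled by the sense table (adjusted p = 0.0263, 0.0263 and 0.0445). In each of the 8 genes the 3 libraries of one genotype lay apart from the 3 of the other, which chance gives for 10% of genes. AC8.7, a pseudogene (X, 230433 to 231365), had antisense counts of 53, 47 and 36 in the single mutant and 3, 3 and 4 in the double mutant (log2 fold change -3.69 ± 0.44, edgeR adjusted p = 0.0924). AC8.12, a pseudogene of the same length nearby (X, 239849 to 240781), had 64, 43 and 31 against 2, 1 and 3 (-4.38 ± 0.54, edgeR adjusted p = 0.0924). F07B7.1 (V, 8872277 to 8873535) and W09B7.1 (V, 8830183 to 8831441), likewise of equal length, had log2 fold changes of -2.15 ± 0.32 and -1.997 ± 0.37 with edgeR adjusted p of 0.186 and 0.472. Genes of equal length and shared family may hold the same reads, so each pair is uncertain as 2 loci. At ads-1 (III, 295654 to 298556), an enzyme of ether lipid synthesis, normalised antisense counts per 1000000 were 13.3 ± 0.424 in the single mutant and 2.27 ± 1.01 in the double mutant (SD, n = 3), with an edgeR adjusted p of 0.186. At osm-3 (IV, 3796300 to 3801052), the kinesin motor of sensory cilia, whose exons overlap K09B3.1 on the other strand, they were 17.2 ± 1.25 and 3.56 ± 1.19 (n = 3), with an edgeR adjusted p of 0.200. At Y54E2A.4 (II, 14754622 to 14778149) they were 68.9 ± 34.6 and 10.9 ± 2.13 (n = 3), with an edgeR adjusted p of 0.472. Y38H6C.21 (V, 20554116 to 20555267) went the other way, with 5, 0 and 1 antisense counts against 36, 18 and 33 (log2 fold change 3.92 ± 0.77, edgeR adjusted p = 0.611).

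**Figure D2:**
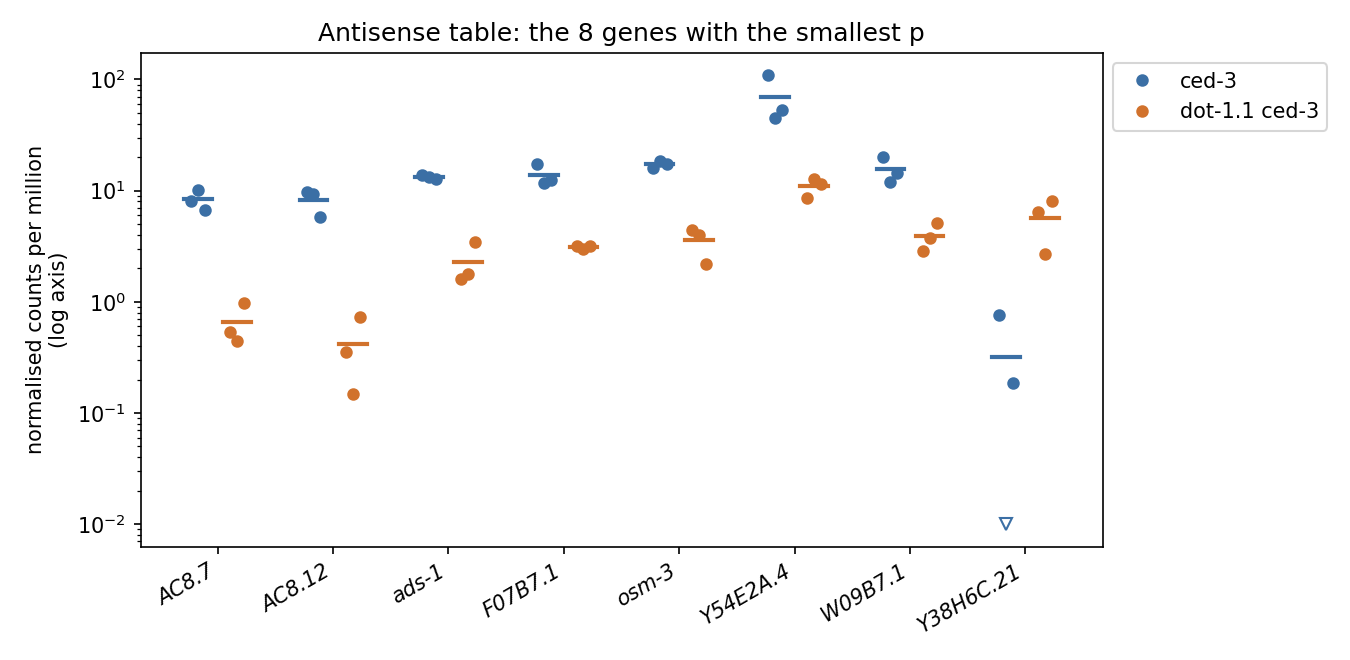
Normalised antisense counts per 1000000 (log axis) in each library for the 8 genes with the smallest p; points are libraries, bars are genotype means, and an open triangle marks a library with 0 counts. AC8.7, AC8.12, ads-1, F07B7.1, osm-3, Y54E2A.4 and W09B7.1 lie lower and Y38H6C.21 higher in the double mutant. None passed the edgeR threshold with the low count filter and TMM normalization from the antisense counts (smallest adjusted p 0.0924).

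Whether antisense counts changed differently from sense counts was tested for 13616 genes, and 0 passed in either direction with edgeR, and 390 were higher and 375 lower at an unadjusted p under 0.05. On simulated data this test recovered 10.6% of 8-fold changes, so it could miss large differences. Its low count filter took both strands together and kept 13616 genes, against 7297 in the antisense test. Genes with few counts on 1 strand were thus simulated too, and recovery among genes with counts on both strands was not measured. Without replicate 3 of the double mutant there were 25 higher and 44 lower, and without any other single library at most 6 higher and 9 lower. Antisense counts made up 20.6% ± 0.869 of both tables together in the single mutant and 20.3% ± 0.573 in the double mutant (n = 3, exact permutation p = 0.6). Over genes with no exon on the other strand they made up 4.20% ± 0.0638 and 3.92% ± 0.616 (n = 3, exact permutation p = 0.7).

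For antisense counts, 22 gene lists had enough members to test, and 0 passed after adjustment with camera. The smallest adjusted p, 0.0670, was shared by muscle genes (12 of 16 members above 0, median log2 fold change 0.50), collagen and cuticle genes (22 of 32, median 0.43) and intestinal genes (6 of 8, median 0.52). With an estimated correlation the smallest adjusted p of any list was 0.799, and it was 0.690 with any 1 library left out and 0.879 without the 2 microRNA-rich libraries, so the calls given next hold at the preset correlation only. For 3 of the 22 lists the median, the mean and the test differed in sign. The muscle and collagen lists passed as higher without replicate 1 or 3 of the single mutant or replicate 3 of the double mutant (adjusted p = 0.0142, 0.0228 and 1.98e-04 for muscle, and 0.016, 0.0157 and 4.81e-04 for collagens), and without the 2 microRNA-rich libraries (adjusted p = 0.00838 for both). The intestinal list passed as higher without replicate 1 or 3 of the single mutant (adjusted p = 0.0233 and 0.0157). The loci of ERGO-1 class small interfering RNAs, with 13 of 13 members below 0 and a median of -0.29 (camera adjusted p = 0.183), passed as lower without replicate 1 of the single mutant, replicate 3 of the double mutant or the 2 microRNA-rich libraries (adjusted p = 0.0142, 1.98e-04 and 0.0135). Across all lists 0 members passed over all genes tested, and 4 passed when adjusted over the list alone. These were mup-4 of the epidermis list, unc-13 and rgef-1 of the neuron list, and C38D9.2, a target of piRNA silencing.

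For sense counts, 7680 genes were tested. With edgeR, 0 genes were higher and 0 lower in the double mutant, and at an unadjusted p under 0.05 there were 440 higher and 184 lower. DESeq2 called 1 gene higher, glb-18, and 0 lower. It called 10 higher and 1 lower when genes without any count were kept in its table, and 0 and 0 when run on the genes edgeR tested. The sense counts of glb-18, chosen after its values were seen because it was the one call, were 5, 2 and 5 in the single mutant and 307, 214 and 1 in the double mutant. Without replicate 3 of the double mutant edgeR called 6 genes higher. The genes with the smallest p did not pass (edgeR adjusted p = 0.590 for all 8). Of these, vit-4, cyp-14A2, egl-18, lron-14 and cut-3 passed with no low count filter, vit-4, cyp-14A2, C50F7.5, C43H6.11 and cut-3 without the 2 microRNA-rich libraries, and vit-4, C50F7.5 and egl-18 with DESeq2 when genes without any count were kept. Among them, vit-4 (X, 3558769 to 3563965), a yolk protein gene, had 3, 0 and 1 sense counts in the single mutant and 12, 24 and 21 in the double mutant. The cytochrome P450 gene cyp-14A2 had 2, 1 and 4 against 16, 21 and 17. C50F7.5 had normalised sense counts per 1000000 of 1.33 ± 0.0702 and 6.21 ± 1.92 (SD, n = 3), and C43H6.11, a non-coding RNA gene, 0.413 ± 0.155 and 1.96 ± 0.269. The log2 fold change of lron-14 was 2.77 ± 0.62. Lower in the double mutant were spr-5, a histone H3 lysine 4 demethylase (log2 fold change -1.99 ± 0.43), egl-18, a GATA factor of the seam cells (-2.34 ± 0.52), and cut-3, a cuticle gene of the embryo (-2.18 ± 0.51). Exons of vit-4, cyp-14A2, lron-14, cut-3 and glb-18 overlap exons of genes on the other strand, so these genes are uncertain, as are the related vit genes where they hold the same reads.

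**Figure D3:**
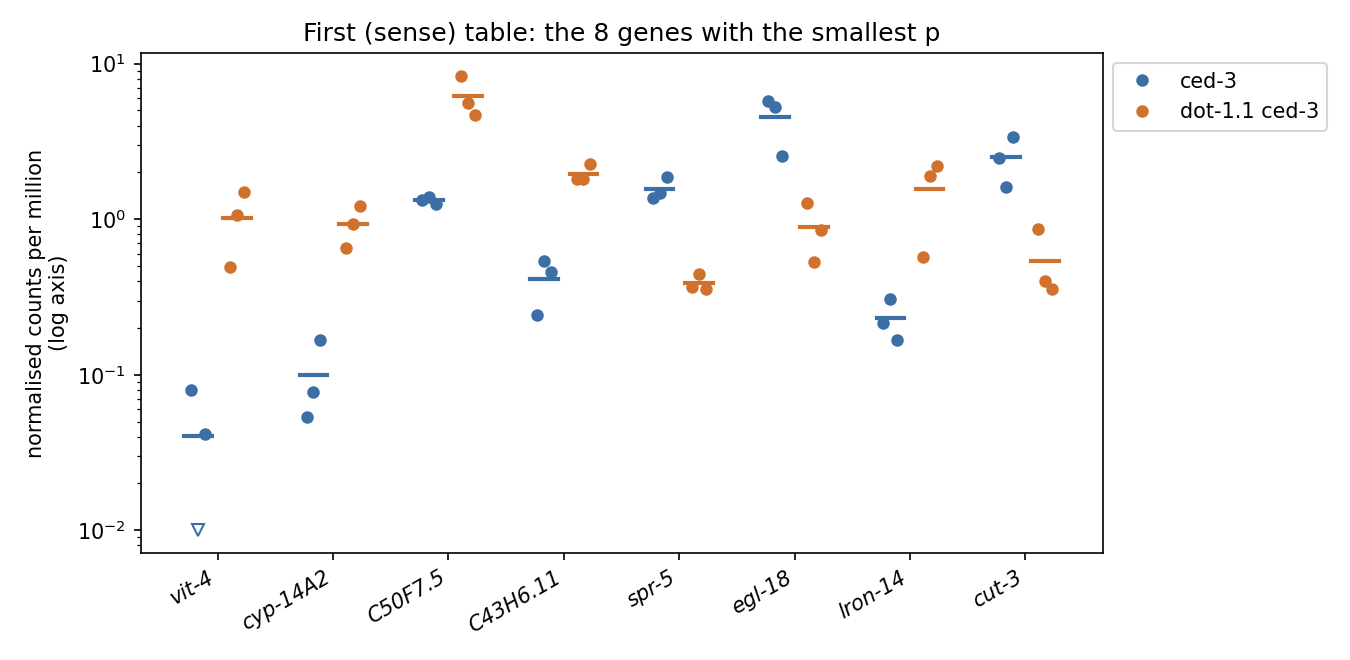
Normalised sense counts per 1000000 (log axis) in each library for the 8 genes with the smallest p; points are libraries, bars are genotype means, and an open triangle marks a library with 0 counts. The genotypes do not overlap at these genes, which chance gives for 10% of genes, and none passed the edgeR threshold with the low count filter and all 6 libraries (adjusted p 0.590).

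Of 23 lists tested in the sense table, 4 rose and 2 fell relative to the other genes with camera at the preset correlation. None of the 6 held with an estimated correlation, where the smallest adjusted p was 0.187. That version rests on the few residual degrees of freedom of 6 libraries, so failing it does not show that a list was unchanged. For chemoreceptor genes the estimated correlation was -0.0081, below the preset 0.01, yet the unadjusted camera p rose from 8.2e-05 to 0.0081. With fry, ribosomal RNA and chemoreceptor genes alone passed (adjusted p = 0.0452 for both), and neither did under microRNA scaling (fry adjusted p = 0.991 for both). The directions of their medians were the same under each of the scalings tried, but the sizes changed. Under library totals and microRNA scaling the median of ribosomal RNA genes was 0.45 and 0.50, against 1.04 with TMM. That of histone genes was -1.42 and -1.35, against -0.95 with TMM. Sense fragments of core and linker histone genes fell, with 70 of 71 members below 0 and a median log2 fold change of -0.95 (camera adjusted p = 1.13e-22; adjusted p = 0.623 with an estimated correlation). Sums over a list, here and below, take in all its genes in the sense counts, tested or not. They are scaled by TMM, and their exact permutation p-values depend on that scaling. For the 80 histone genes the sums were 428 ± 152 counts per 1000000 in the single mutant and 222 ± 26.1 in the double mutant (n = 3, exact permutation p = 0.1). Unscaled, they were 20848, 3376 and 11190 in the single mutant and 5428, 5584 and 2741 in the double mutant, so the genotypes overlapped. Many histone genes are near-identical copies and are uncertain one by one. Ribosomal protein genes fell, with 66 of 78 members below 0 and a median of -0.38 (camera adjusted p = 8.89e-04; adjusted p = 0.955 with an estimated correlation). Over all 80 ribosomal protein genes the sums were 207 ± 89.8 and 164 ± 70.4 counts per 1000000 (n = 3, exact permutation p = 0.6). The call was lost without replicate 1 or 3 of the single mutant or replicate 3 of the double mutant (adjusted p = 0.356, 0.0791 and 0.509).

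Ribosomal RNA genes rose, with 20 of 20 members above 0 and a median of 1.04 (camera adjusted p = 4.81e-07; adjusted p = 0.505 with an estimated correlation), and sums of 47255 ± 11909 and 116005 ± 31688 counts per 1000000 (n = 3, exact permutation p = 0.1). These genes are near-identical copies. The share of sense counts taken by ribosomal RNA genes, which does not use TMM, overlapped between the genotypes (exact permutation p = 0.4, as given above). Intestinal genes rose, with 7 of 11 members above 0 and a median of 1.02 (camera adjusted p = 3.60e-04; adjusted p = 0.459 with an estimated correlation), a call lost without replicate 2 of the single mutant (adjusted p = 0.384) and without the 2 microRNA-rich libraries (adjusted p = 0.273). Summed over all 28 genes of the list, counts per 1000000 were 24.8 ± 16.499 in the single mutant and 28.7 ± 6.93 in the double mutant (n = 3, exact permutation p = 0.9). Its 4 members that passed when adjusted over the list alone were vit-4, vit-6, vit-5 and vit-3, genes for yolk proteins that adults make, while vit-1 and vit-2, chosen after their values were seen, had log2 fold changes of -1.03 ± 0.95 and -1.13 ± 1.01. Chemoreceptor genes rose, with 42 of 55 tested members above 0 and a median of 0.54 (camera adjusted p = 4.74e-04, or 0.187 with an estimated correlation). Summed over all 1626 listed genes, most of them not tested, they came to 126 ± 7.004 and 198 ± 31.1 counts per 1000000 (n = 3, exact permutation p = 0.1). Unscaled, these sums were 4422, 1657 and 3164 in the single mutant and 5701, 3956 and 2623 in the double mutant, so the genotypes overlapped. The later-onset microRNAs, which time larval development, rose with 6 of 6 members above 0 and a median of 1.00 (camera adjusted p = 0.00799; adjusted p = 0.636 with an estimated correlation), and sums of 188 ± 124 and 349 ± 312 counts per 1000000 (n = 3, exact permutation p = 0.6). Of these lin-4 alone passed when adjusted over the list alone, though its exon overlaps F59G1.10 on the other strand, and the call was lost without replicate 1 of the single mutant or replicate 3 of the double mutant (adjusted p = 0.141 and 0.417), and without the 2 microRNA-rich libraries (adjusted p = 0.152). The 17 other lists did not pass, with adjusted p from 0.0653 to 0.935, and for 5 of them the median, the mean and the test differed in sign. With 1 library left out some of them passed at the preset correlation. Collagen and cuticle genes passed as higher without replicate 1 or 3 of the single mutant or replicate 3 of the double mutant (adjusted p = 0.0455, 0.0188 and 0.0136) and muscle genes as higher without replicate 3 of the double mutant (adjusted p = 0.0136). Germline genes passed as lower without replicate 3 of the single mutant (adjusted p = 0.0116), meiosis genes as lower without replicate 1 of the single mutant (adjusted p = 0.0129) and heat shock genes as lower without replicate 1 of the double mutant (adjusted p = 0.0216). The list of all microRNAs and the ERGO-1 class loci also passed with single libraries left out, as given in the closing section. With an estimated correlation no sense list passed with any 1 library left out (smallest adjusted p 0.338). Over all lists, 0 members passed over all genes tested, and 6 passed when adjusted over the list alone: the 4 vit genes and lin-4 above, and egl-18 of the epidermis list, which itself did not pass (adjusted p = 0.109).

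**Figure D4:**
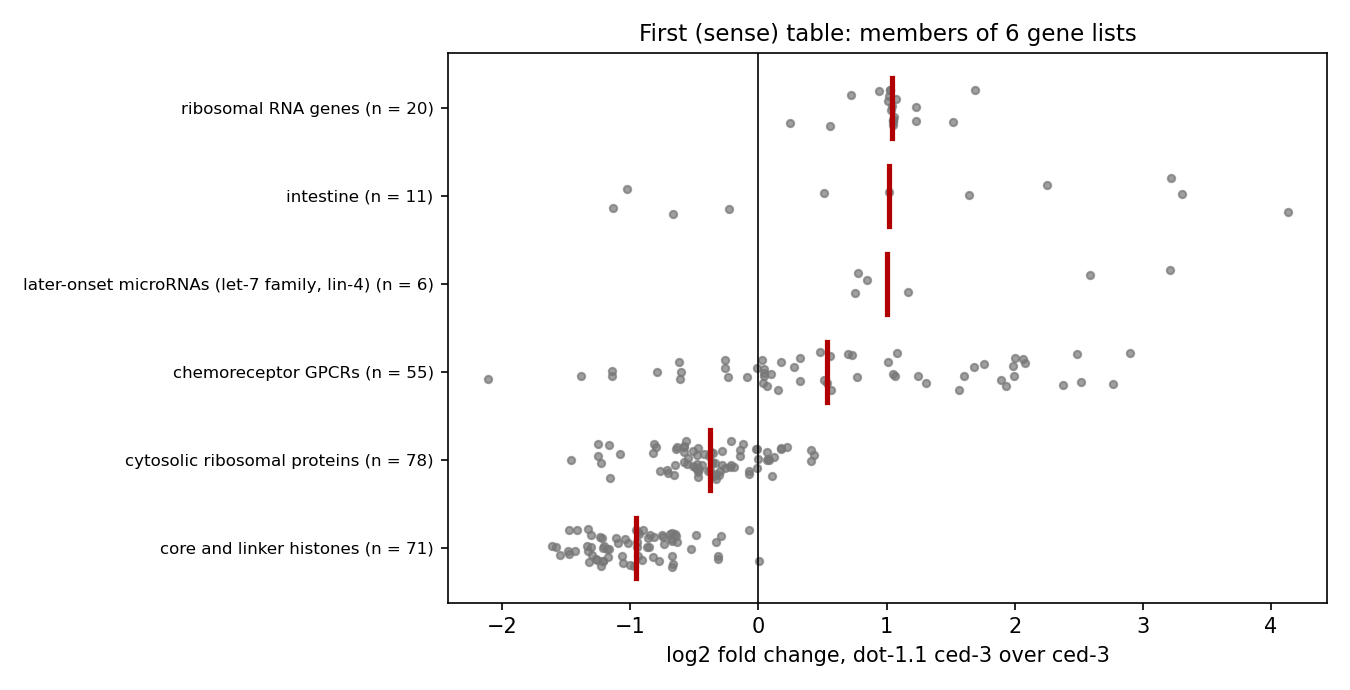
Log2 fold change of each tested member (points) and the median (red bar) of the 6 gene lists past the camera test with a preset correlation in the sense table. Histone genes had a median of -0.95 and ribosomal RNA genes one of 1.04, and no list passed with an estimated correlation.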

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

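The composition covariate (log ratio of protein-coding to microRNA sense counts), leaving out the microRNA-rich pair of libraries, leaving out genes with an exon on the other strand, the DESeq2 versions that kept genes without counts or used the genes edgeR tested, and the estimated correlation under the block or without 1 library were chosen after seeing the data. The edgeR counts of 0 stayed 0 under DESeq2 size factors, library totals, microRNA scaling, the 10-count filter, the fit without robust estimation, without small RNA gene classes, without overlapping genes (antisense) and with the covariate. Antisense genes higher and lower came to 1 and 2 when scaled by the sense table, to 89 and 25 with no low count filter, to 0 and 6 with DESeq2 and with its version that kept genes without counts, and to 1 and 7 with DESeq2 on the genes edgeR tested. Sense genes higher and lower came to 102 and 15 with no low count filter, 1 and 0 with DESeq2, 10 and 1 when it kept genes without counts, 0 and 0 on the genes edgeR tested, and 148 and 13 without the microRNA-rich pair. Leaving out 1 library gave 0 antisense genes each time, 0 to 6 sense genes higher (6 without replicate 3 of the double mutant) and 0 lower, and 0 to 25 higher and 0 to 44 lower in the strand comparison. With 10 counts in 3 libraries of each table the strand comparison stayed at 0. The cause of these changes was not tested, apart from the test on the pair under other observations.

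Whether the replicate numbers pair the samples was not settled. Deviations of same-numbered libraries correlated at 0.646, 0.0143 and -0.136 in the sense table and 0.640, -0.0218 and -0.0336 in the antisense table. Not every library correlated best with its own number. Replicate 2 of the single and 3 of the double mutant correlated at 0.538 (sense) and 0.552 (antisense). Replicate 3 of the single and 2 of the double mutant correlated at 0.0468 (sense) and 0.0320 (antisense). A block by replicate number may therefore hold wrong pairs. Libraries that correlated at 0.646 were both poor in microRNA (77.8% and 72.9% of sense counts), and those at 0.538 both rich in it (92.4% and 89.5%). Pairing therefore cannot be told apart from shared composition. With the replicate number as a block, gene counts stayed at 0, antisense lists higher came to 2 and sense lists to 5 higher and 2 lower, the microRNA list among them (adjusted p = 0.0129; adjusted p = 0.928 with an estimated correlation). No list passed under the block with an estimated correlation (smallest adjusted p 0.715). In the strand comparison the library block already holds the replicate number, so no separate fit was made.

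Antisense lists higher and lower ranged from 0 to 3 and 0 to 1 when 1 library was left out, came to 1 and 0 with the covariate and to 2 and 1 without the microRNA-rich pair, all at the preset correlation. With an estimated correlation no antisense list passed in these settings (smallest adjusted p 0.690 with 1 library left out, 0.693 with the covariate and 0.879 without the pair). Sense lists higher and lower, 4 and 2, came to 0 and 0 with an estimated correlation, alone, with the block or the covariate, or without the microRNA-rich pair or any 1 library, to 2 and 0 with fry, to 0 and 0 with fry under microRNA scaling, and to 2 and 2 without the microRNA-rich pair at the preset correlation. The 2 that passed with fry were ribosomal RNA and chemoreceptor genes, while histone (fry adjusted p = 0.304), intestinal (0.304), ribosomal protein (0.955) and later-onset microRNA genes (0.687) did not. The sense list of microRNAs, not past the threshold (adjusted p = 0.0653), passed as higher without replicate 2 of the single mutant (3.71e-12), replicate 1 (3.97e-10) or 2 (0.00422) of the double mutant and with the covariate (1.31e-05), and as lower without replicate 3 of the double mutant (0.0136), with 0.225 the largest adjusted p over the libraries left out. These calls hold at the preset correlation only: with an estimated correlation the adjusted p of this list was 0.977, 0.691 with the covariate and 0.770 to 0.996 over the libraries left out. The sense list of ERGO-1 class loci, lower in the test (adjusted p = 0.743), passed as higher without replicate 1 of the double mutant (0.0421), with 0.888 the largest, and had an adjusted p of 0.805 to 0.996 over the libraries left out with an estimated correlation.

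Differences in shares (double minus single, percentage points) turned direction without rRNA genes for the antisense share (0.751, from -0.301) and the sense protein-coding share (0.0623, from -0.212). Without the 10 most abundant genes the antisense share came to 0.123 and the antisense microRNA share to -0.0554 (from 0.230). With 1 library left out they ranged from -0.637 to 0.190 (antisense share), -0.0666 to 0.406 (antisense microRNA), -8.74e-04 to 0.00224 (antisense snRNA), -0.00266 to 0.00165 (antisense tRNA), -1.39 to 0.921 (sense protein-coding) and -0.0914 to 0.298 (sense tRNA). Log2 fold changes that turned when 1 library was left out ranged from -0.36 to 0.0028 (ced-3, antisense), -0.10 to 0.30 (zfp-1, antisense), -0.086 to 0.30 (zfp-1, sense), -0.34 to 0.86 (mir-1), -0.49 to 0.63 (mir-35), -0.28 to 0.82 (mir-37), -0.44 to 1.01 (mir-39) and -0.60 to 0.37 (mir-44). Without the microRNA-rich pair mir-44 came to 0.19 and zfp-1 to -0.12 (sense) and -0.084 (antisense). Under library totals and microRNA scaling mir-35 came to -0.11 and -0.014 and sense zfp-1 to -0.42 and -0.37, with -0.22 under antisense scaling and -0.049 with no filter. Those scalings moved the median of all sense genes by -0.31, -0.22 and -0.22, and the antisense median by 0.14 when scaled by the sense table. With the depth, the spread and the 3 libraries per genotype of these data, 1.49% of simulated 2-fold antisense changes and 2.99% of sense changes passed. Depth was not varied alone, so its part was not tested.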

Other observations

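The tests of the 3 patterns below were chosen after the results were seen, and the counts of other splits before. C38D9.2, of the list of loci silenced by piRNAs, had antisense counts of 127, 85 and 89 in the single mutant and 50, 49 and 14 in the double mutant (log2 fold change -1.46 ± 0.39, edgeR adjusted p = 0.846), and all 6 tested members of that list had log2 fold changes below 0 (camera adjusted p = 0.109). Antisense counts of mup-4, an epidermal attachment protein, were 10, 4 and 11 against 41, 27 and 35, and those of myo-3, a muscle myosin chosen after its values were seen, 12, 8 and 6 against 76, 44 and 9. Antisense counts at bli-1, a collagen gene chosen after its values were seen, were 818 in replicate 1 of the double mutant and between 0 and 11 in the other libraries.

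With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The genotypes gave 0 edgeR calls in either table, 0 in the strand comparison and 0 antisense lists, which each of the 10 splits reaches by construction, so these counts of splits say nothing. The highest of the other splits were 95 antisense and 19 sense calls, 122 in the strand comparison and 6 antisense lists. For DESeq2, 3 splits reached the 6 antisense calls and 5 the 1 sense call, with up to 519 and 489 in another split. As many sense lists as the 6 of the genotypes passed in 7 splits, with up to 11 in another split. The split with the most DESeq2 calls set replicate 1 of the single mutant and replicates 1 and 2 of the double mutant against the rest. It gave 519 antisense and 489 sense calls, against 6 and 1 for the genotypes, which points to a structure of the samples other than genotype. Those 3 libraries had the lowest microRNA shares of sense counts (77.8%, 72.9% and 79.0%), against 92.4%, 86.7% and 89.5% in the rest. Whether the microRNA share causes this structure was not tested.

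The first pattern is the lower antisense count at 7 named loci in the double mutant, which edgeR did not call in the test fixed beforehand. DESeq2 called 6 of them, and all 7 on the genes edgeR tested, as did edgeR with no low count filter. Scaled by the sense table, edgeR called AC8.7 and AC8.12 of the 7. Sense reads of a gene on the other strand are argued against, since 0 of the 7 loci had an opposite-strand gene with enough sense counts. A missing locus is argued against for ads-1, osm-3, Y54E2A.4 and the pair F07B7.1 and W09B7.1, whose summed sense counts in the double mutant were 120, 32, 132 and 22 against 61, 57, 242 and 18 in the single mutant (lowest ratio 0.545), unless those counts come from copies elsewhere, while for the pair AC8.7 and AC8.12, with 11 against 33, it cannot be told apart from a change in silencing at counts this low. Reads shared between copies cannot be told apart from separate changes at any of the 7 loci, 4 of which have an equal-length partner among them, since no sequence was used and the treatment of reads that fit several places is not given in the sources used here, and neither can library composition, since the median log2 fold change with the composition covariate (log ratio of protein-coding to microRNA sense counts) was 1.01 times that without it, but that covariate also halved 0 of the 140 other genes that changed as much. An effect of the dot-1.1 mutation on small RNAs at these loci stays open and untested, with 1 strain per genotype.

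The second pattern is mir-70 (V, 6665536 to 6665635), which had 2609 sense counts in replicate 2 of the double mutant and between 202247 and 636583 in the other libraries. Uneven capture of microRNAs in that library is argued against, since mir-70 was the only 1 of 39 abundant microRNAs that lay 10-fold or more below the other libraries, and the next differed by 1.66-fold. The exons of its host gene pmp-5, which do not overlap it, had 12 counts there against 146 to 457 elsewhere, 23.6-fold lower after scaling, as low as no other of the 460 protein-coding genes compared. This is consistent with lower output of the whole locus in that library, and no biological explanation by genotype was tested, since the other double mutant libraries did not share it.

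The third pattern is the 148 higher and 13 lower sense genes called without the microRNA-rich pair. The number of libraries alone is argued against, since 5 of the 8 other ways of leaving out 1 library per genotype gave 0 calls. The other 3 gave 178 (replicate 1 of the single and 3 of the double mutant left out), 71 (replicates 2 and 1) and 2 (replicate 3 of both). Between the libraries left out, 24 of the 178, 13 of the 71 and 0 of the 2 went the same way. For antisense counts, leaving out replicates 2 and 1 gave 63 calls, of which 6 went the same way. Between the libraries of the microRNA-rich pair, 81 of the 161 sense genes went the same way, 69 the other way and 11 were tied, but 98 had under 10 counts there. Of the 63 with at least 10 counts 40 went the same way (63.5%, exact 95% binomial interval 50.4% to 75.3%, over genes that are not independent), so a change shared by all libraries of a genotype cannot be told apart from differences between the other libraries.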
